A study of Homo sapiens with 118 samples.

How the data were processed

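RNA sequencing of human breast cancer cell lines gave 118 libraries in 40 groups, taken from the sample titles and characteristics. The deposited tables hold 1 row for each of 23836 gene symbols per library. Expected counts per gene are RSEM estimates over RefSeq transcripts, per the file headers, and are not normalised. TPM values in the same deposited tables sum to 1000000 in each library. TopHat2, RSEM and the genome build hg19 are named in the submitters' processing notes, without versions, order or parameters. No coordinates are printed, and gene symbols are used as the files give them. The labels do not state that counting used strand, so antisense, overlapping and read-through genes and near-identical copies were treated as uncertain.

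Libraries fall into 6 series that were fitted separately: MCF7 with C70 or C49 over 14 days; C49R and C70R with these compounds for 2 days; E2 for 0, 3 and 6 hours in MCF7, C49R and C70R; MCF7, FULR and TAMR; MCF7 and FULVR with fulvestrant; and 5 lines with C70 for 7 days. Per the labels' protocols, MCF7, C49R and C70R grew in DMEM with serum, and FULVR and TAMR in RPMI with charcoal-stripped serum, with MCF7 in the same stripped medium where the 3 were compared. The labels name FULR and FULVR, and whether these are 1 line is not stated. The library labelled MCF7 KDM5B WT was left out of every comparison because it has no replicate. Depth ran from 6.98 to 76.5 M counts per library, and 2 libraries, both of C49R with E2, had under 10 M. Codes in the names of the deposited tables number 12 and are taken here as sequencing runs. All statements on runs rest on that reading. Files with identical counts number 0.

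Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group with its defaults (a minimum count of 10 and a total of 15), TMM gave the scaling, and dispersions were estimated with robust settings. Quasi-likelihood F-tests on groups gave p-values, adjusted by the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p under 0.05 was called. Each SE is the absolute log2 fold change over the square root of the F statistic. Levels are TMM-normalised CPM, as mean ± SD of 3 libraries. Comparisons number 39, of which 34 set 3 libraries against 3, 4 test a difference between responses of 2 lines, and 1 tests all 5 lines jointly. For the joint test the printed value is the range of responses over the lines, without an SE. A group at 0 counts was set to a floor of 3 counts over the group, and the change is then given as a lower bound. Intervals are 95% intervals from the same fit or, for 1 library, exact Poisson intervals. They cover counting error and the spread between libraries only as far as these libraries show it, since PCR copies without molecular identifiers are not independent molecules.

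Gene lists, 14 in number and 10 to 38 genes long, were fixed before the data were examined: estrogen response, proliferation, interferon response, luminal identity, basal and mesenchymal identity, histone lysine demethylases, cholesterol synthesis, hypoxia response, integrated and unfolded protein stress, p53 targets, receptor tyrosine kinase signalling, metallothioneins, germline genes, and markers of fibroblasts, leukocytes and endothelium. Of their 367 genes, 8 stand in more than 1 list, among them RET and AREG (estrogen response and receptor tyrosine kinase signalling) and XBP1 (estrogen response and protein stress). Of the 22 marker genes, 8 to 17 had enough counts to be tested, so the cell lines themselves express some. Camera in limma 3.58.1 compared each list with all other genes at a preset correlation of 0.01 and with an estimated correlation, and adjusted p over the 14 lists of a comparison. Germline genes passed in none of the 38 comparisons with a list test, the lowest adjusted p being 0.0587 for C70R against MCF7 before E2.

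The genes named were chosen by a rule fixed before the data were examined. In each comparison of 3 with 3 libraries these are the 5 largest rises and 5 deepest falls among called genes with a mean log2 CPM of at least 1, groups that do not overlap and a symbol that is no clone name. The rule adds the 4 members of a described list with the smallest p, ESR1, PGR, GREB1, TFF1, KDM5A, KDM5B, KDM5C, CDKN1A and MKI67 in any comparison, and the 5 genes with the smallest p in a test of a difference between responses. Genes of the Y chromosome were left out. A gene that the rule gave is not reported here. IGF2, the only gene called in FULVR with C70, falls outside the rule.

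Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, the compared groups fitted alone, each replicate number left out in turn, log2(TPM + 1) for the lists, and the full-medium series for C49R and C70R against MCF7. Chosen after the data were examined were the 2 comparisons of C70 with C49 in C49R and C70R, the libraries in doubt that were left out, and the tests of patterns among libraries. Replicate numbers were taken to pair libraries where their deviations from group means correlated above 0.1 in all 3 numbers. This held in 1 of 9 comparisons of the MCF7 time course, in 6 of 6 for C49R and C70R with the inhibitors, in 7 of 8 with E2, in 3 of 3 with FULR and TAMR, in 0 of 3 with fulvestrant and in 3 of 5 with the 5 lines. Distances between libraries are root mean square differences of log2 CPM over genes with a mean above 3.

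The fits were tested on counts simulated for the real genes with 200 genes changed. For MCF7 with C70 at 14 days, 83.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 93.9% of those changed 4-fold were recovered among 15526 genes, and 4.3% of calls were false. For the C70R difference in the 6-hour E2 response, 25.4%, 62.7% and 86.4% were recovered among 15347 genes, and 8.7% of calls were false. In the other 6 comparisons simulated, 3.0% to 7.2% of calls were false. Camera called 20 of 20 lists shifted by 0.50 (log2) and 3 of 260 unshifted lists, on 15641 genes. Simulated genes varied independently and carried no effect shared by the libraries of a run. These rates of false calls therefore do not cover co-regulated lists or run effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.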

Results

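RNA sequencing measured transcript abundance per gene in 118 libraries of human breast cancer cell lines, which fall into 40 groups. Of these groups, 39 hold 3 libraries each, and the group labelled MCF7 KDM5B WT holds 1 library and enters no comparison. The series sets parental lines beside drug-resistant ones, and its title names KDM5B, an enzyme that removes methyl groups from a lysine of histone H3. MCF7, T47D, ZR75 and BT474 carry estrogen receptor, BT474 has amplified ERBB2 as well, and SUM159 is a receptor-negative line. C49R, C70R, FULR, FULVR and TAMR are resistant lines, named in the labels for the compounds C49 and C70, fulvestrant and tamoxifen. C70 and C49, which the labels call KDM5 inhibitors, were given at 10 µM, fulvestrant (an estrogen receptor degrader) at 1 µM and estradiol (E2) at 100 nM. Counts assigned to genes came to 6.98 to 76.5 M (M, 1000000) per library, with a median of 31.9 M. Levels below are mean CPM (TMM-normalised counts per 1000000) ± SD over 3 libraries, and changes are log2 fold changes ± SE from edgeR. "Rose" and "fell" mark an adjusted p under 0.05. For each gene list, the count over all genes tested is followed by the count adjusted over the list alone. The camera test then compares the list with all other genes, and list calls given without a further p also held with an estimated correlation between genes.

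C70 in MCF7 raised interferon-response genes at 2 and 7 days and lowered estrogen-response genes at 2 days, the question being what the inhibitor changes in the parental line. At 2 days 26 of 38 interferon-response genes rose (27 adjusted over the list alone; camera adjusted p = 5.03e-14), and at 7 days 35 rose (36 adjusted over the list alone; adjusted p = 2.23e-43). MX1, an interferon-induced GTPase, went from 10.4 to 19.7 CPM at 2 days (0.91 ± 0.07) and to 22.6 at 7 days (1.11 ± 0.07). At 14 days 8 members rose and 12 fell, and the list test did not pass (adjusted p = 0.851). Of 35 estrogen-response genes, 19 fell at 2 days (21 adjusted over the list alone; adjusted p = 1.31e-14, and adjusted p = 0.102 with an estimated correlation). At 7 days 14 fell and 5 rose (both unchanged when adjusted over the list alone; adjusted p = 7.55e-05, and adjusted p = 0.497 with an estimated correlation). At 14 days 16 fell and 9 rose (17 and 10 adjusted over the list alone; adjusted p = 0.00522, adjusted p = 0.554 with an estimated correlation, and adjusted p = 0.116 on log2(TPM + 1)). Without the untreated replicate 1, 14 fell and 13 rose at 7 days and 14 fell and 17 rose at 14 days. EGR3, an immediate-early transcription factor induced by estrogen, fell from 76.0 ± 3.95 to 41.1 ± 0.739 at 2 days (-0.89 ± 0.04) and stood at -0.61 ± 0.04 and -0.98 ± 0.04 at 7 and 14 days. TFF1, a secreted trefoil peptide, fell by 0.44, 0.50 and 0.74 on the log2 scale at 2, 7 and 14 days. ESR1, the estrogen receptor, fell at 2 days (-0.47 ± 0.05) and 7 days (-0.33 ± 0.05), and its 14-day value of -0.07 ± 0.05 did not pass (adjusted p = 0.209). PGR, the progesterone receptor, fell at 2 days (-0.56 ± 0.14), a call lost without replicate 2 or 3 (both -0.69). Untreated replicate 1 held PGR at 67.96 CPM and untreated replicates 2 and 3 at 41.77 and 40.37, beside 33.17 to 34.32 with C70. The size of this fall therefore rests in part on untreated replicate 1. KDM5B itself rose from 95.6 ± 5.83 to 112 ± 3.22, 110 ± 1.26 and 114 ± 3.51 at 2, 7 and 14 days, with the 2-day call lost without replicate 2 or 3 (both 0.20) and the 7-day call without replicate 2 (0.17). Of 22 basal and mesenchymal genes, 11 rose at 7 days (12 adjusted over the list alone; adjusted p = 7.23e-05), among them CD44 (0.91 ± 0.07) and S100A4 (1.29 ± 0.11). Of 11 markers of fibroblasts, leukocytes and endothelium, 4 rose at 7 days (5 adjusted over the list alone; adjusted p = 0.0262, and adjusted p = 0.0765 with an estimated correlation), with CD68 going from 5.41 to 12.2. By 14 days 11 of 24 luminal genes had risen and 6 had fallen (both unchanged when adjusted over the list alone; adjusted p = 8.27e-05, and adjusted p = 0.053 on log2(TPM + 1)), with MUC1, a cell-surface mucin, at 110 before and 248 after. In the p53-target list 11 of 24 genes fell at 14 days (13 adjusted over the list alone; adjusted p = 0.00983), led by GDF15, a stress-induced cytokine (-0.98 ± 0.06). The largest 14-day rises were CXCL17 (3.79 ± 0.10), the non-coding LINC00494 (3.38 ± 0.21) and MAOB (3.23 ± 0.14), and the deepest falls RASGRP1 (-2.91 ± 0.16) and TGM2 (-2.55 ± 0.18). In all 2465 genes changed at 2 days (1333 higher), 5194 at 7 days and 7101 at 14 days, of 15641 tested. With 1 replicate number left out, the counts spanned 813 to 4010, 2735 to 6059 and 4720 to 7911, and replicates 1 and 2 alone, which share a sequencing run, gave 840, 2825 and 4783. The 2-day interferon count likewise spanned 8 to 29 and the 2-day estrogen count 11 to 19, and differences between time points were not tested.

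Against the mean of the untreated libraries, MCF7 with C49 stood higher in luminal, cholesterol-synthesis and hypoxia-response genes, histone demethylases, PGR and GREB1. Untreated replicates 2 and 3 lay nearer to the C70 than to the C49 libraries of 2 days. Part of these rises could thus belong to culture or preparation and not to C49. GREB1, an estrogen-induced co-regulator, rose from 917 ± 194 to 1142 ± 12.3, 1257 ± 28.4 and 1244 ± 26.5 at 2, 7 and 14 days. PGR rose by 0.52 ± 0.13, 0.77 ± 0.13 and 0.89 ± 0.13, while TFF1 fell by 0.34, 0.54 and 0.36 on the log2 scale. Untreated replicate 1 alone already held GREB1 at 1140 and PGR at 67.96, beside 1128 to 1152 and 68.46 to 75.01 with C49 at 2 days. Without replicate 2 or 3, the GREB1 calls were lost at each time (0.23 to 0.37) and the PGR calls at 2 and 7 days (0.37 to 0.64). Of 19 histone lysine demethylases, 11, 13 and 14 rose at 2, 7 and 14 days (13, 13 and 14 adjusted over the list alone). Their camera adjusted p was 1.98e-06, 7.09e-08 and 4.95e-06, and adjusted p = 0.325, 0.186 and 0.272 with an estimated correlation. KDM5B rose from 95.6 ± 5.83 to 116 ± 2.09, 126 ± 4.12 and 128 ± 2.18, and KDM5A by 0.29 ± 0.06, 0.40 ± 0.06 and 0.35 ± 0.06. KDM5A lost its 2-day call without replicate 2 (0.24) or 3 (0.23) and its 14-day call without replicate 2 (0.25). At 14 days 17 of 24 luminal genes had risen and 2 had fallen (both unchanged when adjusted over the list alone; adjusted p = 7.11e-09), with ELF5, a mammary transcription factor, going from 10.0 to 20.9 and AR, the androgen receptor, from 35.1 to 54.5. Of 24 cholesterol-synthesis genes, 13, 10 and 17 rose (14, 10 and 17 adjusted over the list alone), with SREBF2, the regulator of this pathway, at 0.45 ± 0.06 at 7 days and 0.47 ± 0.06 at 14 days. Adjusted p was 0.00105, 0.0107 and 0.00021, and adjusted p = 0.642, 0.66 and 0.518 with an estimated correlation. Of 30 hypoxia-response genes, 17 rose at 2 days (21 adjusted over the list alone; adjusted p = 1.98e-06, and adjusted p = 0.642 with an estimated correlation), among them ANGPTL4 (0.60 ± 0.10). Interferon-response genes rose at 14 days in 28 of 38 cases (28 adjusted over the list alone; adjusted p = 1.81e-08, and adjusted p = 0.172 with an estimated correlation), with IFI6 at 0.50 ± 0.03. The largest 14-day rises were LINC00494 (3.09 ± 0.21), KCNE4 (2.52 ± 0.13) and CXCL17 (2.50 ± 0.11), and DIO2, a thyroid hormone deiodinase, fell most (-3.60 ± 0.34). EIF4EBP3 and TIAF1, which overlap other genes so that their values are uncertain, led the falls at 2 and 7 days. Genes changed numbered 5496 at 2 days (2934 higher), 6378 at 7 days and 6599 at 14 days. These counts rested on the untreated libraries: replicate 1 stood 0.217 and 0.233 (root mean square log2 distance) from untreated replicates 2 and 3, which stood 0.076 apart. Without a replicate number they spanned 364 to 8171, 2080 to 8745 and 3159 to 8454 (372, 2080 and 3159 in the shared run). The demethylase count spanned 2 to 15 at 2 days and 9 to 14 at 14 days, the cholesterol counts 0 to 18, 1 to 19 and 6 to 20, and the hypoxia count 2 to 23. At 14 days the luminal and interferon counts spanned 11 to 18 and 18 to 30.

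C70 and C49, set against each other at 10 µM in MCF7, differed at each time in estrogen-response and cholesterol-synthesis genes, which stood lower under C70. Of 35 estrogen-response genes, 28, 24 and 21 were lower under C70 at 2, 7 and 14 days (29, 25 and 21 adjusted over the list alone). PGR differed by -1.08 ± 0.14, -1.001 ± 0.13 and -0.65 ± 0.13, ESR1 by -0.55 ± 0.05, -0.58 ± 0.05 and -0.30 ± 0.05, and GREB1 by -0.62 ± 0.09, -0.74 ± 0.09 and -0.72 ± 0.09. Camera adjusted p was 6.54e-14, 2.33e-06 and 2.7e-07, and adjusted p = 0.211, 0.339 and 0.289 with an estimated correlation. For TFF1 the 95% interval of the difference was -0.22 to 0.00 at 2 days and -0.08 to 0.14 at 7 days, and neither difference passed. At 7 days C70 libraries held 2209 to 2539 CPM and C49 libraries 2209 to 2556. These intervals cover the spread between these libraries and not a difference between cultures. At 14 days TFF1 was lower under C70 (-0.38 ± 0.05). KDM5B did not differ detectably at 2 days (interval -0.14 to 0.03) and was lower under C70 at 7 days (-0.20 ± 0.04) and 14 days (-0.17 ± 0.04). Interferon-response genes were higher under C70 at 7 days in 33 of 38 cases (34 adjusted over the list alone; adjusted p = 2.09e-20), with RSAD2, an antiviral enzyme, at 35.8 against 68.9. At 14 days 27 of them were lower under C70 (29 adjusted over the list alone; adjusted p = 6.15e-08, and adjusted p = 0.101 with an estimated correlation), as IFIT2 was (-0.66 ± 0.05). The cholesterol list held 19, 15 and 20 lower genes of 24 (20, 15 and 21 adjusted over the list alone), with SREBF2 at -0.36 ± 0.06, -0.52 ± 0.06 and LDLR, the lipoprotein receptor, at -0.67 ± 0.08 at 14 days. Its adjusted p was 2.5e-06, 0.0142 and 5.08e-06, and adjusted p = 0.211, 0.525 and 0.289 with an estimated correlation. At 14 days 20 of 27 protein-stress genes were lower under C70 (20 adjusted over the list alone; adjusted p = 2.1e-10), among them ATF3 (-1.16 ± 0.10) and ASNS (-0.50 ± 0.04). The proliferation list at 14 days had a median of -0.09 and a mean of 0.00 beside a test pointing up (13 higher, 14 lower; 13 and 15 adjusted over the list alone; adjusted p = 0.039, adjusted p = 0.316 with an estimated correlation, and adjusted p = 0.176 on log2(TPM + 1)). MUCL1, a small secreted mucin, was higher under C70 at 2 days (1.73 ± 0.23). Genes that differed numbered 6775, 8292 and 7722, with 2868 to 7969, 5071 to 9469 and 4791 to 8556 when a replicate number was left out. Over these genes untreated replicates 2 and 3 differed from untreated replicate 1 as C70 did from C49, with slopes of 0.80, 0.56 and 0.48 (genes with a mean log2 CPM above 3). Part of the differences, PGR and GREB1 included, could thus belong to culture or preparation and not to the compound. The shared run gave 3156, 5071 and 4791, and without replicate 2 or 3 the cholesterol count was 10 at 2 days and 10 and 8 at 7 days, and the 14-day count of lower proliferation genes 8 and 9.

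**Figure D1:**
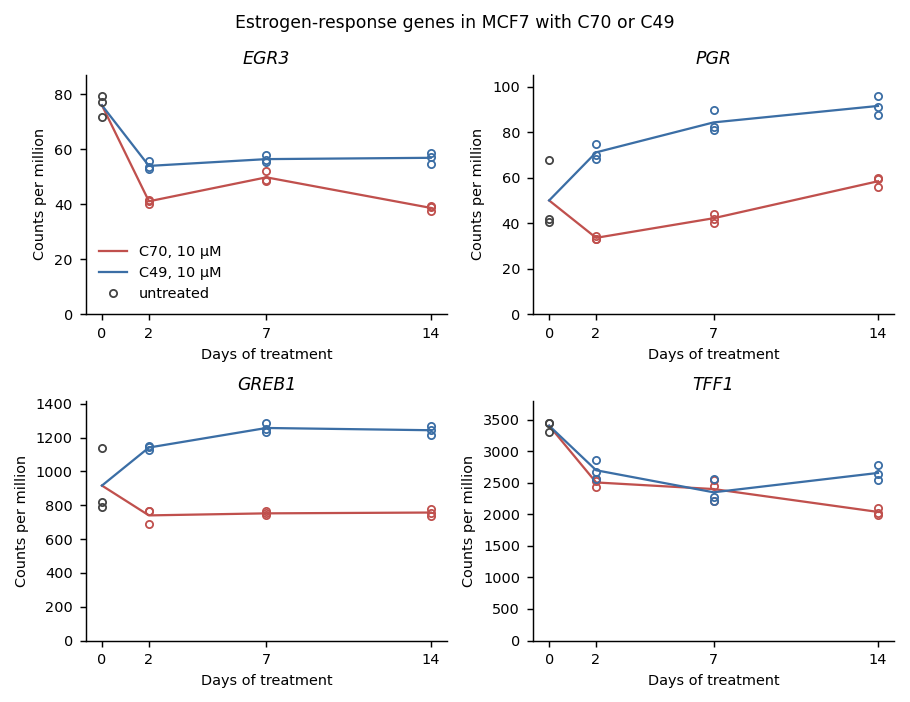
CPM of EGR3, PGR, GREB1 and TFF1 (vertical axes, linear, from 0) in each MCF7 library of the time course against the days of C70 or C49 (horizontal axes), with points for libraries and lines through the group means. EGR3 lies lower under both compounds than in the untreated libraries at each time, and PGR lies higher under C49 than under C70.

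In C70R cells, 2 days of either compound raised interferon-response genes and lowered estrogen-response genes, the question being how a line resistant to the inhibitor responds to it. With C70, 30 of 38 interferon-response genes rose and 4 fell (both unchanged when adjusted over the list alone; adjusted p = 1.77e-25), and with C49, 29 rose and 7 fell (again unchanged; adjusted p = 1.8e-14). CMPK2, an interferon-induced kinase, went from 33.0 to 55.6 with C70 (0.75 ± 0.03) and 56.9 with C49 (0.79 ± 0.03), and RSAD2 from 25.4 to 49.2 and 47.4. Of 35 estrogen-response genes, 27 fell with C70 (27 adjusted over the list alone; adjusted p = 2.18e-21) and 23 with C49 (25 adjusted over the list alone; adjusted p = 5.21e-10). EGR3 fell from 68.7 ± 0.229 to 30.9 ± 0.544 and 36.2, and TFF1 from 2864 ± 78.9 to 1730 ± 41.7 and 1893 ± 58.4. ESR1 fell by 0.22 and 0.09 on the log2 scale with C70 and C49, the second call lost without replicate 1 (-0.08), and GREB1 by 0.25 and 0.20. KDM5B rose from 156 ± 3.60 to 180 ± 5.02 with C70 (0.21 ± 0.03) and to 174 ± 3.61 with C49 (0.16 ± 0.03). Of 24 luminal genes, 15 and 16 fell (unchanged when adjusted over the list alone; adjusted p = 0.0182 with C70 and 0.00988 with C49, and adjusted p = 0.126 and 0.115 on log2(TPM + 1)), with SPDEF, a luminal transcription factor, at 264 before and 156 and 164 after. Of 29 genes of receptor tyrosine kinase signalling, 15 fell with C70 (15 adjusted over the list alone; adjusted p = 0.0204, 0.0692 with the replicate as a block, and 0.0913 on log2(TPM + 1)), led by RET (-0.53 ± 0.03). Among the largest changes, CCDC83 rose with C70 (1.44 ± 0.09) and KRT13 fell with C49 (-2.40 ± 0.26). BIVM-ERCC5 and RAB4B-EGLN2, read-through transcripts whose reads are shared with their component genes, led the lists and are uncertain. C70 changed 9081 of 16534 genes (4693 higher) and C49 10896 (5455 higher). Over 3 libraries 5956 genes had no count in the untreated group, 6379 with C49 and 4236 with C70, so differences in library content run along these comparisons. Each replicate number of this series is a sequencing run of its own, so no run gives a value alone, and once the run is fitted as a block, replicates vary as little as counting error allows (median deviance per degree of freedom 1.04). The adjusted p-values given come from the fit without a block. The replicates of C70R and C49R may be repeated runs of 1 library per condition. In that case SEs and adjusted p-values would not cover repeated cultures.

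C49R cells showed the same directions in both lists, with the estrogen-response genes EGR3, CA12 and PDZK1 among the deepest falls. EGR3 went from 101 ± 0.928 to 36.2 ± 0.302 with C70 (-1.48 ± 0.03) and 43.6 ± 0.0911 with C49 (-1.21 ± 0.03), and CA12, a carbonic anhydrase, from 160 to 80.5 and 99.7. Of 35 estrogen-response genes, 25 fell with C70 (25 adjusted over the list alone; adjusted p = 2.47e-40) and 24 with C49 (24 adjusted over the list alone; adjusted p = 1.86e-36). PGR fell by 0.41 and 0.22 on the log2 scale, ESR1 by 0.49 and 0.27, and TFF1 by 0.55 and 0.49. Interferon-response genes rose in 35 of 38 cases with C70 (35 adjusted over the list alone; adjusted p = 2.47e-40) and in 36 with C49 (36 adjusted over the list alone; adjusted p = 4.47e-44), MX1 from 19.8 to 37.1 and 33.0. Genes of receptor tyrosine kinase signalling fell in 11 and 10 of 29 cases (11 each adjusted over the list alone; adjusted p = 0.000593 and 0.000226), with DUSP4, a phosphatase of the MAP kinase pathway, at -0.63 ± 0.04 and -0.66 ± 0.04. Proliferation genes rose with C49 in 12 of 30 cases (13 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.102 with an estimated correlation), AURKB by 0.18 ± 0.03. Markers of fibroblasts, leukocytes and endothelium rose with C70 in 3 of 10 cases (3 adjusted over the list alone; adjusted p = 0.00739, 0.101 with the replicate as a block, and 0.0592 on log2(TPM + 1)), CD68 from 5.77 to 15.2. The largest rises with C70 were MKX (2.23 ± 0.18) and MMP9 (1.75 ± 0.13), and with C49 MMP9 (1.40 ± 0.13), while TUBA3D fell by 1.47 and 1.07. For KDM5B, C70 gave 0.08 ± 0.03, a call lost without replicate 1 (0.07) or 3 (0.08), and C49 0.05 ± 0.03 (adjusted p = 0.199). C70 changed 6534 genes (3219 higher) and C49 4432 (2301 higher), or 3846 and 1905 without replicate 1, and 7898 for C49 with the replicate as a block. Without replicate 1, 4 rising proliferation genes and 5 falling genes of receptor tyrosine kinase signalling were called with C49. As in C70R, the replicates may be repeated runs of 1 library per condition, which would leave repeated cultures uncovered.

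A comparison added after the data were examined set C70 against C49 in these resistant lines at 2 days, where estrogen-response genes stood lower under C70 in both. In C49R, 17 of 35 were lower (20 adjusted over the list alone; adjusted p = 2.5e-11) and in C70R 11 (11 adjusted over the list alone; adjusted p = 0.00919). EGR3 differed by -0.27 ± 0.03 in C49R and -0.23 ± 0.03 in C70R, ESR1 by -0.22 ± 0.03 and -0.13 ± 0.03, and PGR by -0.20 ± 0.04 (lost without replicate 1, -0.20) and -0.16 ± 0.04. For KDM5B the interval of the difference was -0.01 to 0.11 in C70R and -0.04 to 0.09 in C49R, and the 2-day interval in MCF7 was -0.14 to 0.03. Interferon-response genes were higher under C70 in C49R in 9 of 38 cases (14 adjusted over the list alone; adjusted p = 4.89e-06), led by IFITM1 (0.24 ± 0.03). Of 10 markers of fibroblasts, leukocytes and endothelium, 4 were higher under C70 in C70R (5 adjusted over the list alone; adjusted p = 0.00919), with CD68 at 19.3 against 25.8. In C70R, where the 2 groups also differ in the number of genes without counts, 5598 genes differed and in C49R 1847, or 2675 and 240 without replicate 1, 3494 and 813 without replicate 3, and 9391 and 5792 with the replicate as a block. Without replicate 1 the C49R lists held 6 estrogen-response and 1 interferon-response genes, and the C70R list 5. The limit on the replicates of both lines holds here too.

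A direct test of the difference between lines found genes whose 2-day response to C70 differed between C70R and MCF7. ZMYND8, a reader of histone marks, rose by 0.75 in C70R and by 1.38 in MCF7 (difference -0.63 ± 0.04). CALML5 gave -0.41 in C70R and 0.53 in MCF7, and ALDH3B2 -0.54 and 0.31. Luminal genes responded lower in C70R in 14 of 24 cases (15 adjusted over the list alone; adjusted p = 0.000547), among them KRT19 (difference -0.41 ± 0.06). For C49, interferon-response genes responded higher in C49R than in MCF7 in 31 of 38 cases (33 adjusted over the list alone; adjusted p = 2.36e-30), with CMPK2 at 0.41 in C49R and -0.40 in MCF7. Estrogen-response genes responded lower in C49R in 22 of 35 cases (23 adjusted over the list alone; adjusted p = 4.22e-17), EGR3 at -1.22 and -0.53, and PGR with a difference of -0.73 ± 0.15, lost without replicate 2 (-0.57) or 3 (-0.60). In MCF7, PGR lay at 68.46 to 75.01 CPM with C49, near the 67.96 of untreated replicate 1. Untreated replicates 2 and 3 held 41.77 and 40.37. Part of the differences for C49 could thus belong to the culture or preparation of the MCF7 untreated libraries. The response to C70 differed for 5044 of 16669 genes and that to C49 for 4557. These sets of libraries come from different runs. The replicates of C49R and C70R may be repeated runs of 1 library per condition, so these values may not cover repeated cultures. Without a replicate number the counts spanned 2729 to 2890 and 396 to 5726, and without only the MCF7 untreated replicate 1 they were 4654 and 6896. The C49 estrogen and interferon counts spanned 8 to 26 and 16 to 28, and the luminal count for C70 9 to 13.

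In hormone-deprived medium before E2, both resistant lines stood above MCF7 in proliferation and cholesterol-synthesis genes and below it in basal genes, the question being how the lines differ at rest. Of 30 proliferation genes, 26 were higher in C49R (28 adjusted over the list alone; adjusted p = 3.06e-13) and 28 in C70R (29 adjusted over the list alone; adjusted p = 7.61e-21), with MKI67, a marker of cycling cells, at 213 ± 3.62 in MCF7, 328 ± 9.69 in C49R and 346 ± 14.0 in C70R, and PCNA, a clamp of DNA replication, at 120 and 185 in MCF7 and C49R. Cholesterol-synthesis genes were higher in 17 and 16 of 24 cases (19 each adjusted over the list alone; adjusted p = 9.73e-07 and 2.04e-08). Of 21 basal and mesenchymal genes, 13 and 10 were lower (15 and 12 adjusted over the list alone; adjusted p = 9.73e-07 and 2.17e-05), with CAV1, a membrane scaffold, at 176 in MCF7 and 55.8 in C49R. PGR stood at 17.9 ± 4.04 in MCF7, 69.96 ± 6.11 in C49R (1.97 ± 0.14) and 67.2 ± 6.56 in C70R (1.91 ± 0.14), and CXCL12, an estrogen-induced chemokine, at 8.92, 31.2 and 44.4. Of 35 estrogen-response genes, 17 and 15 were higher and 11 and 13 lower (17, 15, 12 and 14 adjusted over the list alone; adjusted p = 0.000208 and 0.00251, and adjusted p = 0.135 and 0.262 on log2(TPM + 1)). ASCL1, a neural transcription factor, was the highest riser in C49R (5.03 ± 0.17) and stood at 3.78 ± 0.18 in C70R, and ITM2A, a membrane protein, was lower in both (-5.19 ± 0.30 and -5.49 ± 0.30). KDM5B was lower in C49R (-0.33 ± 0.07) and C70R (-0.45 ± 0.07), the first call lost without replicate 2 (-0.29), whereas in full medium, where MCF7 shares no run with C49R and C70R, it was higher (0.63 and 0.55). In full medium 4 proliferation genes were higher and 13 lower in C49R, and 2 and 13 in C70R, with PCNA at -0.22 in C49R. There PGR was higher (1.39 and 1.24), but in the run of C49R and C70R replicate 1 (139 and 127 CPM) the library labelled MCF7 KDM5B WT held 140, so line and run cannot be told apart. In full medium TFF1, higher here (0.89 ± 0.09 and 0.66 ± 0.09), was lower (-0.61 and -0.41) and ASCL1 stood at 0.44 and -0.71. In all 4579 genes differed for C49R and 3943 for C70R of 15514 tested, or 11825 and 12079 in the full-medium series, 6959 and 6488 with the replicate as a block, and at the lowest 2295 and 1848 without replicate 2. Each replicate number was again its own run, so no run gives a value alone.

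E2 in hormone-deprived MCF7 raised nearly the whole estrogen-response list within 3 hours. Of 35 members, 32 rose at 3 hours (33 adjusted over the list alone; adjusted p = 1.59e-195) and 34 at 6 hours (35 adjusted over the list alone; adjusted p = 1.04e-178), and none fell in either comparison. GREB1 went from 456 ± 6.81 to 1138 ± 14.4 and 1505 ± 9.27, PGR from 17.9 ± 4.04 to 96.8 ± 7.90 and 111 ± 17.8, and RET, a receptor kinase, from 21.2 to 81.3 and 97.3. TFF1 stood at 0.28 ± 0.09 at 3 hours (adjusted p = 0.056) and rose by 0.49 ± 0.09 at 6 hours. The largest rises at 6 hours were GATA4 (5.89 ± 0.37), from 0.112 to 6.94 CPM, and PTGES, which makes prostaglandin E (3.94 ± 0.15). At 3 hours TNFRSF11B, a decoy receptor, fell most (-1.55 ± 0.10). Interferon-response genes fell at 6 hours in 12 of 38 cases (13 adjusted over the list alone; adjusted p = 5.28e-06), STAT2 by 0.52 on the log2 scale. Of 30 proliferation genes, 8 rose at 6 hours (10 adjusted over the list alone; adjusted p = 0.00777, and adjusted p = 0.0533 with an estimated correlation), CDC6, a licensing factor of DNA replication, by 0.69 ± 0.07. Of 30 hypoxia-response genes, 6 rose at 3 hours and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.04), with the glucose transporter SLC2A1 at 0.83 ± 0.08. KDM5B fell at 6 hours from 209 ± 8.72 to 170 ± 8.59 (-0.30 ± 0.07), a call lost without replicate 2 (-0.27). Changed genes numbered 929 at 3 hours (598 higher) and 2040 at 6 hours (1108 higher). With the replicate as a block, where the 3-hour numbers pair libraries, the first count was 2136, and left-out replicates gave 329 to 927 and 759 to 2191. The interferon count fell to 3 without replicate 2.

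In C49R and C70R, E2 raised the same list, from a higher resting level of PGR and RET. In C49R 29 of 35 members rose at 3 hours and 28 at 6 hours (33 and 32 adjusted over the list alone; adjusted p = 1.66e-156 and 1.37e-141), and in C70R 32 and 34 rose (34 each adjusted over the list alone; adjusted p = 6.01e-167 and 7.29e-159). GREB1 went at 6 hours from 664 ± 11 to 1761 ± 56.8 in C49R and from 626 ± 5.29 to 1897 ± 33.6 in C70R, and PGR from 69.96 ± 6.11 to 196 ± 28.1 and from 67.2 ± 6.56 to 240 ± 30.8. IGFBP4, a binding protein of insulin-like growth factors, rose by 3.05 ± 0.10 and 3.24 ± 0.11 at 6 hours, and SEMA3G, a secreted semaphorin, by 3.55 ± 0.25 and 3.07 ± 0.24. Interferon-response genes fell at 6 hours in 8 and 14 of 38 cases (14 and 16 adjusted over the list alone; adjusted p = 0.000124 and 4.93e-07), with STAT2 at -0.38 ± 0.06 and -0.50 ± 0.06. In each line 8 of 30 proliferation genes rose at 6 hours (9 in C49R and 8 in C70R adjusted over the list alone; adjusted p = 0.0191 and 0.0349). For these, adjusted p = 0.09 and 0.123 with an estimated correlation, and CDC6 stood at 0.54 ± 0.07 and 0.68 ± 0.07. At 3 hours TNFRSF11B fell by 1.88 and 1.91, and GRHL3, an epithelial transcription factor, by 1.68 and 1.82. Neither line gave a KDM5B call at 6 hours in the edgeR fit without a block (-0.18 ± 0.07, adjusted p = 0.102, and -0.09 ± 0.07, adjusted p = 0.532). The replicate numbers pair libraries at 6 hours in both lines, and these values do not use that pairing. C49R counted 967 genes at 3 hours and 1529 at 6 hours, and C70R 1118 and 1798. With the replicate as a block these were 2076, 3447, 2316 and 3639, and they fell to 377, 488, 461 and 634 without replicate 2. Without that replicate the 6-hour counts were 2 and 5 falling interferon genes in C49R and C70R and 3 rising proliferation genes in each, and 4 falling interferon genes in C49R without its 2 libraries under 10 M counts.

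A test of the difference between lines in the 6-hour E2 response named 30 genes for C49R and 26 for C70R. On the log2 scale CXCL12 rose less in both, by 1.27 in C49R and 1.29 in C70R against 2.11 in MCF7 (differences -0.84 ± 0.09 and -0.82 ± 0.09). CXCL12, RET and PGR stood higher in C49R and C70R than in MCF7 before E2. A smaller fold change from a higher start need not be a smaller gain in CPM. RET rose by 1.37 in C49R against 2.19 in MCF7, and HSPB8, a small heat-shock protein, by 1.81 against 2.51. In C70R, THBS1, a matrix glycoprotein, rose by 1.01 against 0.31, and UBR4, a ubiquitin ligase, gave 0.07 against -0.49. The estrogen-response list responded lower in C49R (6 of 35 lower; 14 lower and 2 higher adjusted over the list alone; adjusted p = 2.91e-22) and in C70R (2 lower; 4 lower and 3 higher adjusted over the list alone; adjusted p = 3.88e-05). PGR gave a difference of -1.16 ± 0.20 in C49R, and -0.80 ± 0.20 in C70R, which did not pass (adjusted p = 0.138). DESeq2 called this C70R difference. Replicate numbers pair libraries in most comparisons of this series, and the edgeR values given do not use that pairing. With the replicate as a block the counts were 164 and 130. Without 1 replicate number they were 1 to 13 and 0 to 2, and 1 to 4 lower estrogen-response genes were called for C49R and 0 to 1 for C70R. The calls of HSPB8 were then lost without replicate 1 (-0.73) or 2 (-0.67), of PGR without 2 (-1.15) or 3 (-1.11), of CXCL12 without 2 (both -0.81), of THBS1 without 2 (0.66) or 3 (0.71) and of UBR4 without any 1 of them (0.52 to 0.57).

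**Figure D2:**
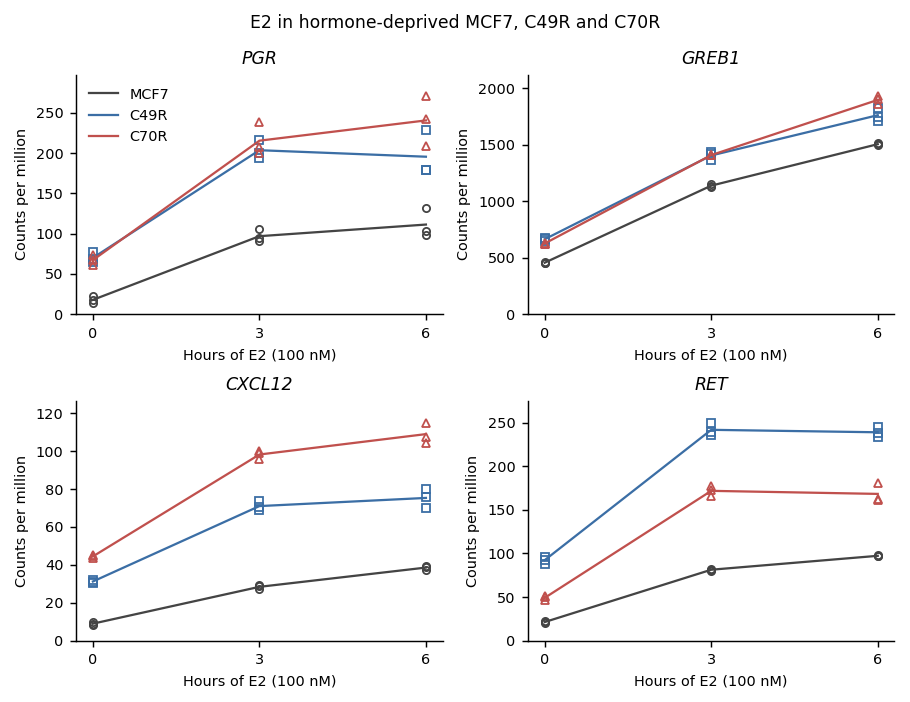
CPM of PGR, GREB1, CXCL12 and RET (vertical axes, linear, from 0) in each library of MCF7, C49R and C70R against hours of E2 (horizontal axes), with points for libraries and lines through the group means. Each gene lies higher at 3 and 6 hours than at 0 hours in each line, and PGR starts higher in C49R and C70R than in MCF7.

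FULR and TAMR stood lower in interferon-response, estrogen-response and basal genes, the question being how lines resistant to fulvestrant and tamoxifen differ from the parent. All 38 interferon-response genes were lower in FULR (38 adjusted over the list alone; adjusted p = 7.33e-104) and 34 in TAMR (34 adjusted over the list alone; adjusted p = 1.32e-20). IFIT3, an antiviral protein, stood at 136 in MCF7, 3.53 in FULR and 42.5 in TAMR. Of 35 estrogen-response genes, 29 were lower in FULR and 20 in TAMR (29 and 20 adjusted over the list alone; adjusted p = 3.15e-14 and 6.06e-08), with CTSD, a lysosomal protease, at 1567, 366 and 498. GREB1 stood at 209 ± 4.53, 10.1 ± 2.03 and 3.01 ± 2.19, its TAMR difference of -6.00 ± 0.36 being -6.91 without replicate 1. TFF1 was higher in FULR (0.69 ± 0.08) and lower in TAMR (-1.90 ± 0.08), and RET was higher in both (1.51 ± 0.07 and 2.40 ± 0.07). ESR1 was lower (-0.29 ± 0.05 and -0.27 ± 0.05), both calls lost without replicate 3 (-0.28 and -0.26). Basal and mesenchymal genes were lower in 11 and 10 of 17 cases (11 each adjusted over the list alone; adjusted p = 1.7e-07 and 2.07e-07), CAV1 by 3.01 and 3.29. Hypoxia-response genes went apart: 19 of 30 were higher in FULR (19 adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.0876 with an estimated correlation), and 23 lower in TAMR (24 adjusted over the list alone; adjusted p = 2.11e-13). Another 7 were lower in FULR and 1 higher in TAMR. Set against each other, FULR was higher than TAMR in 24 of these 30 (24 adjusted over the list alone; adjusted p = 3.87e-28), with NDRG1 at 13.8 in TAMR and 136 in FULR. CA9, a hypoxia-induced carbonic anhydrase, stood at 0.0216 CPM in TAMR and 10.1 in FULR. KDM5B was lower in TAMR than in MCF7 (-0.30 ± 0.07) and than in FULR (150 ± 9.34 against 192 ± 12.8, 0.36 ± 0.07), both calls lost without replicate 3 (-0.30 and 0.36). LRFN5 (7.71 ± 0.18) and SYT13 (6.53 ± 0.14) led the rises in FULR and CACNB2 (5.48 ± 0.14) stood among those in TAMR. ACTG2, a smooth-muscle actin, went from 62.0 to 0.140 CPM in FULR. In FULR 7517 of 14779 genes differed from MCF7, in TAMR 6254, and 6237 between them, or 4637, 3360 and 3039 without replicate 3. Each replicate was its own run, so no run gives a value alone, and the labels give stripped medium for MCF7, FULVR and TAMR without naming FULR.

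Fulvestrant for 7 days in MCF7 lowered every member of the estrogen-response list and of the proliferation list. All 35 estrogen-response genes fell (35 adjusted over the list alone; adjusted p = 1.3e-55), GREB1 from 1186 ± 33.3 to 72.3 ± 1.82, TFF1 from 2199 ± 23.7 to 202 ± 15.5 and PGR from 64.0 ± 0.738 to 4.53 ± 0.492. All 30 proliferation genes fell (30 adjusted over the list alone; adjusted p = 1.32e-50), MKI67 from 673 ± 27 to 206 ± 13.1, while CDKN1A, an inhibitor of the cell cycle, rose from 59.8 ± 2.41 to 120 ± 2.66. KDM5B rose from 90.8 ± 0.602 to 214 ± 1.14 (1.24 ± 0.04), KDM5A by 0.41 ± 0.06 and KDM5C by 0.40 ± 0.04. Of 24 luminal genes, 17 rose (17 adjusted over the list alone; adjusted p = 0.00654, and adjusted p = 0.266 with an estimated correlation), ELF3 from 44.1 to 118. Another 6 luminal genes fell. GABBR2 rose most among genes with counts in both groups (5.87 ± 0.08), and AFF2, at 0 in each untreated library, was at least 3.80 log2 units higher, taking 3 counts over the group as the floor. BMPER (-6.11 ± 0.27) and IGSF1 (-5.67 ± 0.10) fell most. Fulvestrant for 2 days in FULVR, a different time, lowered 20 of 24 cholesterol-synthesis genes (22 adjusted over the list alone; adjusted p = 5.28e-50), ACAT2 from 71.4 to 33.5. It raised 22 of 27 protein-stress genes (23 adjusted over the list alone; adjusted p = 9.05e-45), DDIT4 from 28.3 to 56.6. There 33 of 38 interferon-response genes fell (36 adjusted over the list alone; adjusted p = 4.69e-36), HERC6 from 29.5 to 13.5, and 19 of 30 proliferation genes (21 adjusted over the list alone; adjusted p = 7.08e-13), KIF20A by 0.38 on the log2 scale. TFF1 rose from 313 ± 17.4 to 516 ± 25.1, and 8 of 35 estrogen-response genes rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 7.71e-05). ESR1 fell from 60.8 ± 3.18 to 34.7 ± 0.713, and KDM5B rose by 0.16 ± 0.04, a call lost without replicate 1 (0.15) or 2 (0.17). Untreated FULVR stood below MCF7 in 33 of 35 estrogen-response genes (33 adjusted over the list alone; adjusted p = 2.18e-81), GREB1 at 9.84 ± 0.173, and above it in KDM5B (154 ± 0.789). PGR stood at 64.0 ± 0.738 in MCF7 and 0.01 in FULVR. Counts of changed genes were 10322 of 14928 for MCF7, 2485 for FULVR (857 to 3054 when a replicate number was left out) and 10763 between the untreated lines. In FULVR, the count was 1895 without the treated replicate 3, in which 18605 genes had counts against 16969 and 16894 in its group. The interferon count spanned 19 to 33 and the proliferation count 8 to 20 when a replicate number was left out, and estrogen members that rose 5 to 10. All 12 libraries share a run, and the labels leave open whether both lines had the same medium.

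C70 for 7 days raised S100A4 in T47D, ZR75 and BT474 and other basal and mesenchymal genes in T47D and ZR75. Estrogen-response genes went down in T47D and up in BT474. S100A4, a calcium-binding protein of motile cells, went from 50.7 to 195 in T47D, 5.07 to 20.6 in ZR75 and 3.57 to 13.3 in BT474. In T47D 21 of 35 estrogen-response genes fell (21 adjusted over the list alone; adjusted p = 3.81e-15), PGR from 267 ± 9.34 to 82.4 ± 2.62 and GREB1 from 298 ± 3.05 to 144 ± 3.46. In BT474 24 rose (25 adjusted over the list alone; adjusted p = 2.1e-09), PGR from 164 ± 11.7 to 269 ± 4.69 and GREB1 from 142 ± 1.63 to 288 ± 4.17. In ZR75 9 rose and 14 fell (adjusted p = 0.465), with GREB1 at 442 ± 3.05 and 239 ± 5.56. Basal and mesenchymal genes rose in 9, 10 and 6 of 28 cases in T47D, ZR75 and BT474 (9, 10 and 5 adjusted over the list alone; adjusted p = 0.000369, 2.05e-05 and 0.0108, the last with adjusted p = 0.236 with an estimated correlation and 0.116 on log2(TPM + 1)). Of all 17124 genes tested, 3067, 3065 and 3433 rose in these lines. The share of the list in BT474 thus lies near that of all genes. Interferon-response genes rose in 15 of 38 cases in T47D and 18 in ZR75 (15 and 18 adjusted over the list alone; adjusted p = 0.000449 and 9.83e-06), IFI6 in ZR75 from 18.4 to 82.4. With an estimated correlation, adjusted p = 0.498 and 0.533 for these. Proliferation genes fell in 28, 12 and 15 of 30 cases (29, 12 and 15 adjusted over the list alone; adjusted p = 2.05e-17, 0.000922 and 0.000395), MCM6 by 0.48, 0.21 and 0.60. For ZR75 and BT474, adjusted p = 0.533 and 0.703 with an estimated correlation. Hypoxia-response genes rose in 20 of 30 cases in T47D and 14 in ZR75 (20 and 14 adjusted over the list alone; adjusted p = 2.39e-07 and 0.000263). Among 17 markers of fibroblasts, leukocytes and endothelium, 5 and 4 rose in T47D and ZR75 (unchanged when adjusted over the list alone; adjusted p = 0.0095 and 0.0124, adjusted p = 0.134 and 0.24 with an estimated correlation, and adjusted p = 0.205 and 0.0844 on log2(TPM + 1)), CD68 from 5.19 to 11.8 and 17.4 to 65.0. KLK12, a kallikrein protease, led the rises in BT474 (5.32 ± 0.20), MZB1 stood among those in ZR75 (3.51 ± 0.49), and SCGB2A2, a mammary secretoglobin, fell in ZR75 (-2.55 ± 0.11) and BT474 (-2.39 ± 0.12). KDM5B rose by 0.19 ± 0.04, 0.13 ± 0.04 (lost without replicate 1, 0.15, or 3, 0.12) and 0.49 ± 0.04. Counts were 6126, 5585 and 6840 of 17124 genes, and 3780, 3190 and 4495 at the lowest with a replicate number left out. Each replicate was its own run. Left-out replicates took the interferon counts to 9 to 25 and 11 to 29, the T47D basal count to 5 and the ZR75 proliferation count to 5.

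In SUM159, C70 raised KRT6A, KRT5 and KRT14, keratins of basal epithelium, and lowered cholesterol-synthesis genes. KRT6A went from 188 to 490 and KRT14 from 3.58 to 10.4, within 9 of 28 basal and mesenchymal genes that rose and 4 that fell (10 and 6 adjusted over the list alone; adjusted p = 0.000809, adjusted p = 0.0822 with an estimated correlation, and adjusted p = 0.229 on log2(TPM + 1)). Of 25 cholesterol-synthesis genes, 15 fell (15 adjusted over the list alone; adjusted p = 7.46e-08, and adjusted p = 0.0822 with an estimated correlation), INSIG1 from 213 to 134. Metallothioneins, which bind metals, rose in 4 of 5 cases (5 adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.0504 with an estimated correlation), MT1E from 17.6 to 41.4. KDM5B rose from 36.7 ± 0.477 to 45.8 ± 1.30, and GDF5, a growth factor, stood among the deepest falls (-2.75 ± 0.19). In FULVR 1 gene passed with all libraries, IGF2, at 0 counts in each untreated library and 1.202 ± 0.63 CPM after C70. IGF2 shares exons with INS-IGF2 and is uncertain, and it is named because the count was 1. DESeq2 called 3 genes, and 1114 had an unadjusted p under 0.05. The interferon list pointed down with no member called (adjusted p = 5.01e-09, and adjusted p = 0.521 with an estimated correlation). The C70 response of replicate 2 ran opposite to that of replicates 1 and 3, and without it 4501 genes passed. In those 2 replicates per group, 32 of 38 interferon-response genes fell (34 adjusted over the list alone; adjusted p = 2.86e-75), IFIT1 from 108 to 35.0. Of 30 proliferation genes, 20 rose (22 adjusted over the list alone; adjusted p = 3.91e-13), AURKA from 145 to 185. TP63, a transcription factor of basal cells, stood at 0.12 and 6.05, and KDM5B rose by 0.20 ± 0.04. SUM159 gave 4616 genes (2015 higher), and 2662 and 2303 without replicate 1 or 3. In FULVR 0 genes passed when its 2 groups were fitted alone or replicate 3 was left out, and no run holds more than 1 library per group.

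The response to C70 differed between the 5 lines for 8259 genes in a joint test. S100A9 and S100A8, calcium-binding proteins of inflamed epithelium, gave 2.33 and 2.48 in T47D, 2.45 and 2.73 in ZR75, 1.84 and 2.85 in BT474, and -1.80 and -0.997 in SUM159. FULVR with all its libraries gave 0.29 and -1.91, neither called (adjusted p = 0.791 and 0.701). SCD, which makes monounsaturated fatty acids, gave 1.02 in BT474 and -0.19 in T47D, and BHLHE40, a circadian repressor, 1.84 and -0.28. KDM5B passed as well, with a range over lines of 0.40 whose lower end is FULVR (0.09 with all its libraries, and 0.20 without replicate 2). PGR passed too, at -1.70 in T47D and 0.71 in BT474. Its range of 2.50 (3.87 without replicate 1 and 4.72 without replicate 2) ends at SUM159 (0.81 ± 0.72, adjusted p = 0.467), where PGR lay at 0 to 0.554 CPM, so the range rests on few counts. The smallest counts were 4778 and 4448 without replicate 1 or 3, and 10073 genes passed without the libraries of FULVR replicate 2.

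**Figure D3:**
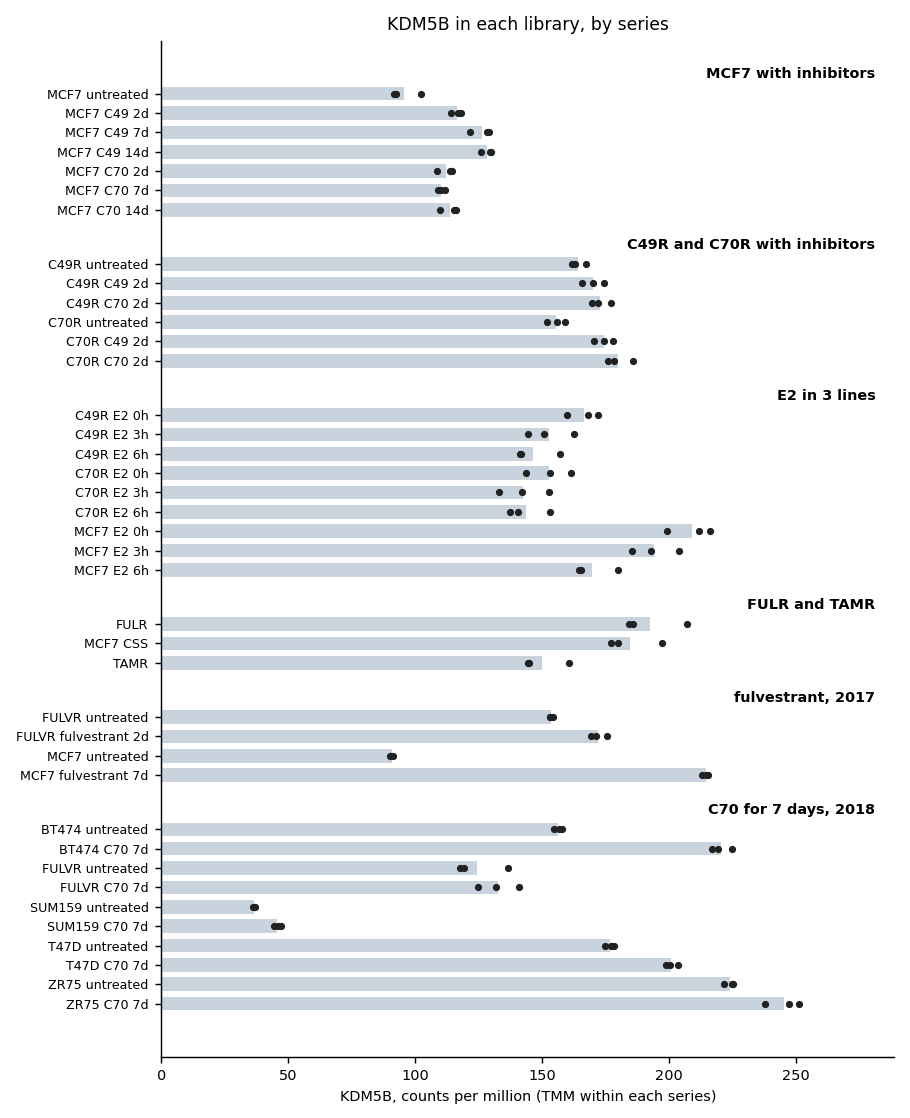
KDM5B in CPM (horizontal axis, linear, from 0) in each library of every group in a comparison, with points for libraries and bars for the group mean, TMM-normalised within each series. In the series with fulvestrant the fulvestrant-treated MCF7 libraries average 214 against 90.8 in untreated MCF7.

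**Figure D4:**
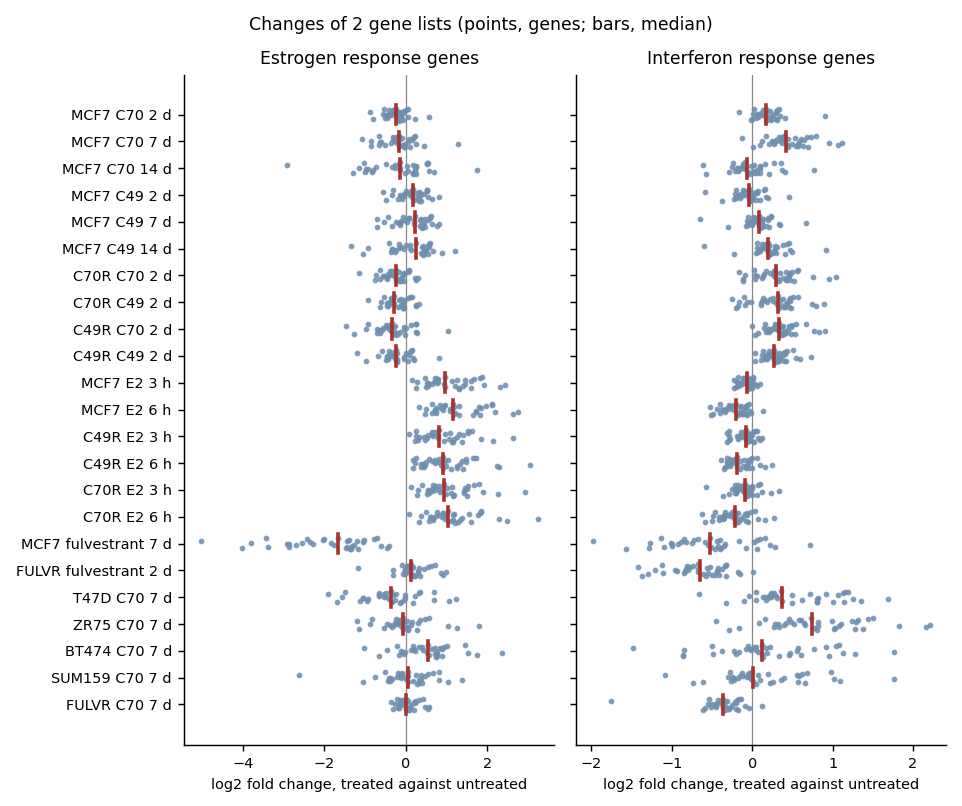
Log2 fold changes of estrogen-response and interferon-response genes (horizontal axes) in each comparison of treated with untreated libraries, with points for genes and bars for the median, and FULVR with C70 drawn with all its libraries. The medians after fulvestrant in MCF7 lie at -1.67 and -0.52.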

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

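The tests of the 3 patterns among libraries were chosen after the results were seen, whereas the tests of differences between lines and the counts over other splits of the libraries were planned. No group holds 4 to 10 libraries, so no library was tested for standing apart from its group.

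ZMYND8 rose less with C70 in C70R than in MCF7 (difference -0.63), and PLEKHG4 (-1.07), B4GALT1 (-0.45), CALML5 (-0.94), ALDH3B2 (-0.85) and KRT19 (-0.41) also responded lower. They stand here because a test of the difference between the lines called 5044 genes and the luminal list (adjusted p = 0.000547). PLEKHG4 gave 1.03 in MCF7 and -0.04 in C70R. Over 30 splits of these libraries, 3 gave as many genes and the highest other gave 6554, so chance is not excluded by them. That split mixed untreated and C70 libraries in MCF7 and kept them apart in C70R, so it counts the C70 response of C70R itself, a structure of the samples.

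With C49, EGR3 fell further in C49R than in MCF7 (difference -0.69), and TM4SF1 (-1.70), JARID2 (-0.60), B4GALT1 (-0.39) and PGR (-0.73) responded lower, while CMPK2 responded higher (0.80). The test of the difference called 4557 genes, the interferon-response list (adjusted p = 2.36e-30) and the estrogen-response list (adjusted p = 4.22e-17). TM4SF1 rose by 1.09 in MCF7 and fell by 0.61 in C49R. Of 30 splits only the real one gave as many genes, the highest other being 3505. That split kept C49 and untreated libraries apart in C49R and mixed them in MCF7. Such splits remove the response of a line, so they cannot decide whether chance explains a difference between responses. The MCF7 untreated libraries enter this difference, and without replicate 2 or 3 it held 619 and 396 genes.

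On the log2 scale, RET (-0.82), CXCL12 (-0.84), TMEM164 (-0.69), HSPB8 (-0.70), KCNK5 (-0.96) and PGR (-1.16) responded lower to 6 hours of E2 in C49R than in MCF7. RET, CXCL12 and PGR stood higher in C49R before E2. The test of the difference called 30 genes and the estrogen-response list (camera adjusted p = 2.91e-22). In C70R, CXCL12 rose less (-0.82), and THBS1 (0.70), HUWE1 (0.41), UBR4 (0.56) and RNF213 (0.39) responded higher, among 26 genes and the estrogen-response list (adjusted p = 3.88e-05). KCNK5 rose by 1.19 in MCF7 and gave 0.22 in C49R, which did not pass (edgeR adjusted p = 0.247). In each line 6 of 30 splits gave as many genes, with 964 and 1043 as the highest others, so chance is not excluded. Those splits mix the E2 libraries of 1 line and not of the other, so they count the E2 response, a structure of the samples. TMEM164 and KCNK5 lost their calls without replicate 1 (-0.67 and -1.01) or 2 (-0.70 and -1.01), and HUWE1 and RNF213 without any 1 replicate number (0.38 to 0.44 and 0.35 to 0.42).

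Responses to C70 differed over the 5 lines for S100A9 and S100A8, with ranges of 4.25 and 4.75 (log2), and for ARHGDIB (1.93), SCD (1.21), BHLHE40 (2.12), PGR (2.50) and KDM5B (0.40). FULVR, with its replicate 2 in doubt and no call, is the lower end for S100A8 (-1.91) and KDM5B (0.09), and SUM159, without a call, the upper end for PGR (0.81). ARHGDIB fell by 1.09 in BT474 and rose by 0.84 in ZR75. The joint test called 8259 genes, the highest other of 30 splits gave 3303, and only the real one gave as many. These splits mix C70 and untreated libraries within lines, which removes the responses themselves. They therefore cannot decide whether chance explains a difference between lines.

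KDM5B stood at 144 CPM in the single library labelled MCF7 KDM5B WT (exact Poisson 95% interval 141 to 147), above the 91.4 to 102 of the MCF7 untreated libraries, all scaled to library totals. It shares a run with none of these, and the C49R and C70R untreated libraries of its run held 163 and 156 (TMM-normalised), so the run goes with the difference. It is given because no comparison uses this library, and KDM5A (60.3) and ESR1 (186) also lay above the untreated ranges of 32.3 to 41.0 and 106 to 125, so the higher level is not particular to KDM5B. With 1 library there is no replicate check.

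In comparisons of 3 with 3 libraries only 10 splits exist, too few for a share under 0.05. In 23 of these 34 comparisons the real split called 929 to 10896 genes and the others 0, and in 4 the real split called 1847 to 6840 and the highest other 1. For C70 in MCF7 the real and highest other counts were 2465 and 12 at 2 days and 5194 and 93 at 7 days. Replicate numbers paired libraries only at 7 days, and the highest of the 3 other splits that part as many pairs gave 4. For SUM159 the counts were 4616 and 28. For C49 in MCF7 they were 5496 and 3358, 6378 and 4191, and 6599 and 1186 at 2, 7 and 14 days, each highest other setting the untreated replicate 1 beside C49 replicates 2 and 3. For C70 in FULVR the real split called 1 gene and the split that exchanges the replicate 2 libraries 5641, which points to a structure of the samples, and 4 of the 10 splits gave as many as the real one.

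In FULVR the response of replicate 2 to C70 ran opposite to that of replicates 1 and 3 (r across genes -0.82 and -0.78, against 0.81 between 1 and 3; genes are not independent replicates). Replicate 2 of this series has another date, but in T47D, ZR75, BT474 and SUM159 its response followed that of the other replicates with a slope of 0.86 or more, which argues against the date. A culture that did not respond to C70 would give a slope near 0, and the slope was -0.91. An exchange of labels between the 2 libraries of replicate 2 stays open: each lay nearer to the other condition at 90.7% or more of 3651 genes, those with a mean log2 CPM above 3 among the 4608 called with replicate 2 left out in every line. No biological explanation was tested, as the design names none for 1 replicate.

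The MCF7 untreated replicate 1 lay with the C49 libraries (distance 0.138, and 0.252 to those with C70 at 2 days), and untreated replicates 2 and 3 with the C70 libraries (0.161 each, and 0.257 and 0.271 to C49). With the codes taken as runs, the distances argue against the sequencing run. Untreated 1 and 2 share a run, yet their distance was 2.86 times that of untreated 2 and 3, of different runs. A candidate explanation is that untreated replicate 1 was cultured or prepared with the C49 libraries and the others with the C70 libraries. Untreated 2 and 3 differed from untreated 1 as C70 did from C49, with slopes of 0.80, 0.56 and 0.48 at 2, 7 and 14 days over 5198, 6241 and 5613 genes. Across these genes, which are not independent replicates, r was 0.91, 0.79 and 0.68. The sign was the same in 95.6%, 85.8% and 79.4% of them. No biological explanation was tested. Part of the differences between C70 and C49 in MCF7 could belong to the arm and not to the compound. This holds over these genes and not only for PGR and GREB1.

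In C49R and C70R with the inhibitors, the libraries of 1 condition differed little once the run was fitted as a block, with a median Poisson deviance per degree of freedom of 1.04 against 2.28 to 2.91 in the other series. Without a block, pairs of these libraries differed beyond counting error (chi-square per degree of freedom 2.86 to 7.37). Greater depth as the reason is argued against by thinning each library to 10 M counts, after which the value was 0.962 and the lowest other 1.45. A candidate explanation is 1 library per condition sequenced in 3 runs, for which 1.04 with the block lies at the level of sampling noise. Whether a library of low complexity lies behind the C70R untreated libraries stays open: 56.5% of 62 genes missing from replicate 1 were missing from replicates 2 and 3 too, beside 25% of 24 such genes in C70R before E2, and the bounds set were 90% and 50%. No biological explanation was tested. If 1 library per condition was sequenced in 3 runs, all SEs and adjusted p-values of this series would describe libraries and not repeated cultures. Those of EGR3 and TFF1 are examples, and values with a replicate left out would have the same limit.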

How the results depend on the processing

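The settings that leave out libraries in doubt, and every setting for C70 against C49 in C49R and C70R, were chosen after the data were examined. Over all settings, 292 values of named genes were recomputed 2439 times, of which 2351 kept their direction and their side of the threshold, 68 lost a call, 11 gained one and 9 changed sign. RLE scaling left all 292 in place and moved the median of all genes by at most 0.02 (log2, largest for SUM159). DESeq2 left 290 in place, with TFF1 after 3 hours of E2 in MCF7 (0.27) and PGR in the difference between C70R and MCF7 (-0.81) gaining calls. Without the low-count filter 291 kept their calls, the exception being KDM5B in C49R with C70 (0.07). With the replicate number as a block 287 stayed in place and 5 gained calls. A value that did not pass without the block may therefore pass with it. The number of genes called was recomputed 327 times over 39 comparisons and stayed within 1.5-fold in 226 cases.

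With the compared groups fitted alone, fewer libraries estimate the spread. The counts for C70 in MCF7 were then 710 at 2 days and 2727 at 7 days, of which 709 and 2719 were among the genes called before, and those for C49 were 1546 and 3081. For E2 they were 531 and 1199 in MCF7 at 3 and 6 hours, 628 in C49R and 1047 in C70R at 6 hours, and 11 and 5 for the differences of C49R and C70R from MCF7. In FULVR with C70 the count was 0, and DESeq2 gave 3.

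With the replicate number as a block, the count for C49R with C49 was 7898, for C70 against C49 9391 in C70R and 5792 in C49R, and for C49R and C70R against MCF7 before E2 6959 and 6488. For E2 it was 2136 and 4165 in MCF7 at 3 and 6 hours, 2076 and 3447 in C49R, and 2316 and 3639 in C70R, with 164 and 130 genes for the differences between lines. For T47D, ZR75 and BT474, whose numbers also pair libraries, the block gave 6041, 5456 and 6723, slightly below the counts without it. MCF7 at 6 hours is the 1 E2 comparison in which the numbers did not pair libraries. Those 2 differences also moved to 53 and 58 with DESeq2 and to 17 and 10 without the low-count filter, and the second to 15 with RLE scaling. The cause was not tested.

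Taking C49R and C70R against MCF7 from full medium, where the lines share no run with MCF7, gave 11825 and 12079 genes, with 2183 and 2130 of the former calls in the same direction. TFF1 changed sign (-0.61 and -0.41), as did KDM5B (0.63 and 0.55), PCNA in C49R (-0.22) and ASCL1 in C70R (-0.71). The cause was not tested. Sign changes near 0 were those of ESR1 in MCF7 after 14 days of C70 without the untreated replicate 1 (0.008, the range over left-out replicates being -0.11 to 0.008) and of TFF1 in C70 against C49 at 7 days without replicate 2 or 3 (range -0.032 to 0.17).

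With a replicate left out 2 libraries or more remain in each group, and the fits rest on fewer libraries. For MCF7 with C70 the counts ran from 813 to 4010, 2735 to 6059 and 4720 to 7911 at 2, 7 and 14 days, and with C49 from 364 to 8171, 2080 to 8745 and 3159 to 8454. The highest values are those without replicate 1. For C70 against C49 they ran from 2868 to 7969, 5071 to 9469 and 4791 to 8556. C49R gave 3846 to 6120 with C70 and 1905 to 4128 with C49, and C70 against C49 gave 2675 to 5112 in C70R and 240 to 1822 in C49R. The 2-day differences from MCF7 ran from 2729 to 2890 for C70R and from 396 to 5726 for C49R, and without only the MCF7 untreated replicate 1 they were 4654 and 6896. Before E2, C49R and C70R against MCF7 gave 2295 to 4835 and 1848 to 4113. For E2 the counts were 329 to 927 and 759 to 2191 in MCF7, 377 to 1029 and 488 to 1645 in C49R, and 461 to 1092 and 634 to 1874 in C70R. The 6-hour differences gave 1 to 13 for C49R and 0 to 2 for C70R. FULR and TAMR gave 4637 to 8027 and 3360 to 7081 against MCF7 and 3039 to 6746 against each other. FULVR with fulvestrant gave 857 to 3054. With C70, T47D gave 3780 to 5867, ZR75 3190 to 5510, BT474 4495 to 6752, SUM159 2303 to 4506, FULVR 0 to 4608, and the joint test 4448 to 8461, or 10073 without only the FULVR replicate 2 libraries.

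The list tests of 111 described lists were lost in 37 cases with an estimated correlation, in 13 cases on log2(TPM + 1), with adjusted p from 0.053 to 0.262, and in 2 cases with the replicate as a block. The 13 were luminal genes in MCF7 with C70 at 14 days and in C70R with either compound, proliferation in C70 against C49 at 14 days, receptor tyrosine kinase signalling in C70R with C70, estrogen response in MCF7 with C70 at 14 days and in C49R and C70R before E2, the fibroblast, leukocyte and endothelium markers in C49R with C70, T47D and ZR75, and basal genes in BT474 and SUM159. Depth limits the C49R libraries with E2 most, of which 2 hold 6.98 and 8.94 M counts, and without these the counts of C49R with E2 stayed within 1.5-fold. Genes near 0 are limited by counts, as with IGF2 in FULVR, which rests on 86 counts.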

Other observations

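C70 for 7 days raised 236 genes and lowered 303 in all of T47D, ZR75, BT474 and SUM159, where independent lists of the same sizes would share 13 and 14 of 17124 genes. T47D and ZR75 shared 1407 higher genes against 549 for independent lists, and 166 genes higher in T47D were lower in ZR75. Genes are not independent of each other, so these counts are descriptions.

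After 6 hours of E2, MCF7 and C70R shared 807 higher and 525 lower genes (76 and 44 for independent lists), and MCF7 and C49R 693 and 457 (65 and 37). For C70 at 2 days, MCF7 and C49R shared 921 higher genes (269 for independent lists) and C70R and C49R 1325 (914 for independent lists), with 570 genes higher in C70R and lower in C49R. FULR against MCF7 and FULVR against MCF7, from different series, shared 2290 higher genes (1288 for independent lists) and 550 genes higher in FULR and lower in FULVR.

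C70R untreated libraries held no counts for 5956 genes over 3 libraries and C70R with C49 for 6379, against 4236 with C70 and 4309 to 4444 in the C49R groups. Of genes with no count in C70R untreated and 5 counts or more in each C70R library with C70, which number 70, 57.1% had counts in all C70R libraries of the E2 series at 0 hours. In the library labelled MCF7 KDM5B WT, PGR stood at 140 CPM, GREB1 at 1820 and KDM5C at 133, beside 39.9 to 67.8, 788 to 1140 and 104 to 108 in the MCF7 untreated libraries, which are of other runs.

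FULVR with fulvestrant replicate 3 had counts for 18605 genes, whereas its group mates had 16969 and 16894 and the untreated FULVR libraries 16858 to 17163. Over 7915 genes at or near 0 in the untreated libraries, replicate 3 held 230.0 CPM and the others 75.2 and 73.1.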
